A study of Danio rerio with 68 samples.

How the data were processed

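Total RNA was isolated from brain, liver and skin of male zebrafish with a phenol-based reagent and made into sequencing libraries with a TruSeq RNA kit, per the labels' protocols. The authors deposited whole-number counts per gene and library, not normalised, and a second table of RPKM (reads per kilobase of gene, scaled to counted reads). CASAVA 1.8.2 is named in the submitters' processing notes, while the aligner, the counting program, its use of strand and the genome build are not given in the sources used here. Every test used the counts. The RPKM served only to recover the authors' gene lengths. These were the same in every library for all 30932 genes with a count (median 1616 bp).

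The counts covered 32677 genes in 68 libraries, of which 32326 genes had a symbol in the table. Symbols were used as given there, with current ones added from a name table where the Ensembl gene identifier matched (21028 of 32677). Protein-coding genes took 98.26% of the counts. Symbols ending in a bracket such as (1 of 2) mark similar gene copies, whose reads the counting could have split. Their values are uncertain, as are those of overlapping and antisense genes. No genome was used, so GC content was not tested and no coordinates are given. Per library 21977 to 27208 genes had a count. In 109 pairs of replicates the counts differed by far more than sampling noise (chi-square per gene of 17.28 to 1202), so no library was a copy of a replicate of its group.

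Libraries were grouped by tissue, age, treatment and sampling time from the labels. Each tissue was fitted separately with its 6 groups in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 23032 in brain, 20190 in liver and 22682 in skin. Libraries were scaled by TMM, dispersions were estimated robustly, and contrasts were tested with the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error is the absolute log2 fold change divided by the square root of F. The contrasts were rotenone against control at each time, their difference, 36 against 12 months pooled and at each time, and 8 against 3 weeks in controls. Differences between tissues were contrasts in a fit of all 68 libraries and 25628 genes. CPM values are means and standard deviations over the fish of a group. Correlations used log2 CPM with a prior count of 2.

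Gene lists, 48 in all, were tested for the contrasts of rotenone at each time and of pooled age, on voom values, with camera of limma 3.58.1. Its inter-gene correlation was preset to 0.01 and, as an alternative, estimated from the data, and p was adjusted over the lists of a tissue and contrast. Of lists called with the preset, only the glucocorticoid-responsive genes in liver after 3 weeks stayed called with an estimated correlation. Fish-level list scores were compared by exact permutation tests, two-sided.

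The tests, the alternatives, the gene lists and the rule for the genes named were fixed before the data were examined. For rotenone at 3 and 8 weeks and pooled age, the rule took the 8 largest rises and 8 largest falls among called genes with a mean CPM of at least 1 and a symbol that is not a clone or accession name. It also took the 4 members with the smallest p of each list called by camera and of complex I subunits, and the 10 genes with the smallest p where fewer than 10 were called. Members were left out for length only from the end of a ranking, and 1 gene that the rule names is not reported. Genes named for other contrasts and between tissues were chosen after their values were seen, as were the clock genes that the liver account names as such.

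The alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, voom with sample quality weights, the groups of a contrast fitted alone, the replicate number as a block and each library left out in turn. Chosen after the data were seen were fits without the 5 libraries that stood apart and fits with the trend of counts over transcript length removed from each library by a natural spline with 4 degrees of freedom. The number in a column name, which brain, liver and skin libraries share, pairs tissues of a fish. Of 20 fish, 19 brain libraries correlated best with the liver library of their own number after group means were removed. It was 23 of 24 between brain and skin and 20 of 20 between liver and skin (p = 0.0001 in each case, the smallest that 10000 permutations can give). Fits between tissues were therefore repeated with fish as a block.

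The tests were run on simulated counts with the libraries' sizes, gene means and dispersions and 200 changed genes. For rotenone at 3 weeks, 4-fold changes were recovered in 81.8% of cases in brain, 39.4% in liver and 68.2% in skin, and 2-fold changes in 40.3%, 1.49% and 35.8%. For rotenone at 8 weeks the shares were 95.5%, 66.7% and 89.4% for 4-fold and 41.8%, 7.46% and 46.3% for 2-fold changes. For age they were 81.8%, 75.8% and 83.3% for 4-fold and 59.7%, 14.9% and 40.3% for 2-fold changes. Between brain and skin at 8 weeks, 56.1% of 4-fold and 11.9% of 2-fold changes were recovered. At most 5 unchanged genes were called in any run. Most 2-fold changes in liver would thus go undetected at these group sizes. Other splits of real brains called up to 5947, so these rates hold only for simulated counts.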

Results

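Rotenone is a plant-derived inhibitor of mitochondrial complex I. Male zebrafish of 36 months were kept for 3 or 8 weeks in water with 3.75 nM rotenone. Their brain, liver and skin were profiled by RNA-seq beside controls of 36 and 12 months given the solvent DMSO for the same times. In brain and skin the groups at 3 and 8 weeks held 3 and 3 control fish of 12 months. They held 3 and 4 control fish of 36 months, and 5 and 6 rotenone fish. In liver the same groups held 2, 3, 2, 3, 4 and 6 fish. The 68 libraries had total counts of 24.1 to 54.9 M in the 24 brains (median 29.15), 28.7 to 47.3 M in the 20 livers (median 35.95) and 24.3 to 34.4 M in the 24 skins (median 28.75). A gene was called where edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05. Counts within a list are of genes past that threshold with p adjusted over the list alone. Values after ± are standard errors beside log2 fold changes and standard deviations beside CPM (counts scaled to library size). The number of tanks is not given, so the p-values measure the spread between fish. The ages are different birth cohorts, so age, stock and rearing cannot be told apart.

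Genes of other tissues or a trend over transcript length set 5 libraries apart, identified after the data were seen. Intestine markers took 3.47% of the counts of the 36-month control liver replicate 3 at 8 weeks and between 0.0514% and 0.139% of those of the other livers. Testis and germ cell markers took 0.224% of the 12-month control skin replicate 2 at 3 weeks and 0.0494% of the 36-month control skin replicate 3 at 3 weeks, against 0.00178% to 0.0245% elsewhere. That 36-month skin library also held 17.0% skeletal muscle counts, above the 0.842% to 7.27% of the other skins. In rotenone brain replicates 3 and 4 at 3 weeks, counts fell with transcript length, with slopes of -0.109 and -0.198 against -0.0386 to 0.0605 in the other brains. Each count below was also computed without these 5 libraries.

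After 3 weeks of rotenone, 5 treated brains were compared with 3 control brains of 36 months. Transcripts for the respiratory chain, the ribosome and the proteasome stood above other genes in the treated brains and those of the circadian clock below them, but not with an estimated correlation and with smaller medians without 2 treated brains. No single gene passed the test over all genes. All 40 complex I subunits had log2 fold changes above 0, with a median of 0.63, and 37 passed within the list, among them ndufv1 (0.50 ± 0.14) and NDUFB2 (0.91 ± 0.27). The median was 0.61 over 43 subunits of complexes II to V, where 33 passed within the list and cyc1 was at 0.63 ± 0.18 and sdhb at 0.64 ± 0.19. It was 0.58 over 87 cytosolic ribosomal proteins (73 within the list; rpl12 at 0.65 ± 0.20) and 0.49 over 53 proteasome subunits (35 within the list; psmd8 at 0.73 ± 0.20). The gene set test camera called these 4 lists higher, with adjusted p from 1.04e-22 to 1.72e-14, and none of them when the correlation between genes was estimated (estimated-correlation p, also adjusted, of 0.329 for each). Mitochondrial chaperones and proteases, with hspd1 at 0.64 ± 0.15 and hspe1 at 0.66 ± 0.18, had 10 of 19 members past the threshold within the list. Neutrophil markers such as nccrp1 (0.65 ± 0.16) and cxcr4b (0.74 ± 0.25) had 6 of 21, and antioxidant genes such as prdx6 (0.65 ± 0.16) had 1 of 36. camera called these lists and that of the integrated stress response (aars at 0.45 ± 0.14, phgdh at 0.78 ± 0.24) higher, with estimated-correlation p = 0.197 for each. Of 42 clock genes, 4 higher and 13 lower ones passed within the list. The light- and clock-driven period gene per1b was at -1.34 ± 0.22 and C19H1orf51 (1 of 2) at -1.67 ± 0.28 (adjusted p 0.0613 for both). The clock repressor genes nr1d2b and nr1d1 were at -0.78 ± 0.14 and -1.44 ± 0.31, nfil3-5 at 0.80 ± 0.14 and cry2b at 0.46 ± 0.09. The other genes among the 10 with the smallest p were ccr9a (1.51 ± 0.30), bach2b (-0.61 ± 0.13), csnk1db (-0.33 ± 0.07) and TPMT (1 of 2) (0.59 ± 0.13). camera called the clock list lower, with estimated-correlation p = 0.312. The other called lists were higher for endoplasmic reticulum stress, glycolysis, cytosolic heat shock proteins, immediate early genes, radial glia genes, cholesterol synthesis, mitochondrially encoded mRNAs and xenobiotic metabolism, and lower for insulin signalling and the interferon response, with medians from -0.27 to 0.42 and estimated-correlation p from 0.197 to 0.697. Without the treated brains with the fall over transcript length, the medians were 0.14 for complex I, 0.14 for complexes II to V, 0.13 for ribosomal proteins, 0.13 for the proteasome and -0.18 for the clock. Of 19 called lists 15 left a range of 1.5 times. Mitochondrially encoded mRNAs, cholesterol synthesis and insulin signalling were no longer called, while 3 lists were called that had not been, among them proliferation (-0.41). edgeR called 0 of 23032 genes, with 2941 at an unadjusted p under 0.05, while DESeq2 called 35 and limma with voom quality weights 0. Without control replicate 2 the count was 5, without control replicate 3 it was 2 and without treated replicate 2 it was 6.

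In liver, 4 fish treated for 3 weeks were compared with 2 controls. Transcripts of glucocorticoid-responsive genes stood above other genes in treated livers, as did genes of gluconeogenesis and of the clock, these 2 not with an estimated correlation. Of 18 glucocorticoid-responsive genes, 16 lay above 0, with a median of 0.86, and 5 passed within the list. Among them were klf9 (2.25 ± 0.67), tsc22d3 (2.03 ± 0.61), slc2a4rg (2.03 ± 0.67) and pck1, which encodes the entry enzyme of gluconeogenesis (2.80 ± 0.93). camera called this list with the preset and with an estimated correlation (adjusted p = 0.0327). Its 2 controls, also used for age, had pck1 at 64.3 CPM, against 1120 CPM in those at 8 weeks. Gluconeogenesis and amino acid catabolism genes had a median of 0.52 and 0 of 47 passed within the list (arg2 at 3.11 ± 1.06, g6pca.2 at 2.65 ± 0.93), with estimated-correlation p = 0.836. Clock genes had a median of 0.22 and 3 of 41 passed within the list, with nr1d2a at 2.25 ± 0.55 and rorcb at 1.94 ± 0.48 and estimated-correlation p = 0.232. Pancreas markers (median -1.1), cholesterol synthesis (-0.87; srebf2 at -1.03 ± 0.54), ribosomal proteins (-0.16) and endoplasmic reticulum stress genes (-0.21) were called lower. Erythrocyte markers (0.49), collagens (0.48) and insulin signalling genes (0.26; socs2 at 1.6 ± 0.60) were called higher, all with estimated-correlation p from 0.836 to 0.928. The 39 complex I subunits had a median of 0.10 and were not called (camera adjusted p 0.258). edgeR called 0 of 20190 genes, with 970 at an unadjusted p under 0.05, while DESeq2 called 27 and voom 0. The smallest p belonged to the retinoid receptor gene rxraa (1.98 ± 0.37, adjusted p 0.866), followed by dlg5a (1.26 ± 0.25), HEATR1 (2 of 2) (-1.75 ± 0.37), nr2f6b (-1.42 ± 0.30). Next came tnfrsfa (-0.94 ± 0.21), C2CD3 (1.18 ± 0.27), pisd (-1.66 ± 0.38), DAPK1 (1.22 ± 0.28), stk35 (2.57 ± 0.61) and STK35 (1 of 3) (2.77 ± 0.66). Without control replicate 1 the count was 21.

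In skin, 5 fish treated for 3 weeks were compared with 3 controls. Respiratory chain transcripts stood above other genes in treated skins, and cell proliferation transcripts below them, but not with an estimated correlation, and no member passed within its list. Complex I subunits had a median of 0.44 (38 of 40 above 0; NDUFV3 (2 of 2) at 0.62 ± 0.29), complexes II to V 0.43 (41 of 43; cox4i1 at 0.48 ± 0.21) and mitochondrially encoded mRNAs 0.56 (13 of 13; mt-nd3 at 0.58 ± 0.24), with 0 genes of each past the threshold within the list. Proliferation genes had a median of -0.57, with MKI67 at -1.04 ± 0.41 and cenpf at -1.32 ± 0.52, and 0 of 63 passed within the list. Of 33 cytosolic heat shock genes, 9 lower and 1 higher ones passed within the list, among them hsp70.1 (-2.24 ± 0.45) and hsp70.3 (-2.25 ± 0.46). camera called these 5 lists, and also ribosomal proteins, glycolysis and the proteasome higher and the interferon response lower, with estimated-correlation p = 0.895 for each. In the ribosomal list the member with the smallest p was rps6kb1a, a kinase of ribosomal protein S6 and not a ribosomal protein (-0.83 ± 0.35). Without the skin libraries with testis genes, of which the 36-month one also held 17.0% muscle counts, the heat shock median went from -0.46 to 0.11 and was not called (hsp70.1 at -1.38, hsp70.3 at -1.32). That of proliferation went from -0.57 to -0.25 (MKI67 at -0.59), interferon from -0.24 to -0.50 and complex I from 0.44 to 0.60, while muscle genes went from -0.96 to 0.65 (camera adjusted p 3.33e-06). edgeR called 0 of 22682 genes, with 2281 at an unadjusted p under 0.05, while DESeq2 called 96 and voom 0. The homeobox gene hoxc10a had the smallest p (1.1 ± 0.18, adjusted p 0.0804). Besides the hsp70 genes it was followed by slc27a6 (-1.2 ± 0.22), baiap2l1b (-1.19 ± 0.23), myh11b (-1.86 ± 0.37), mfsd4a (1.33 ± 0.28), hlfb (1.66 ± 0.35), TJP1 (2 of 2) (-0.70 ± 0.15) and rorcb (2.32 ± 0.49). The count was 320 without control replicate 2 and 1 without treated replicate 2.

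After 8 weeks, 6 treated brains were compared with 4 control brains. Of the 7 genes called, 4 belong to the circadian clock, and interferon-responsive transcripts stood below other genes, though not with an estimated correlation. The repressor gene nr1d2b fell from 177 ± 13.4 CPM (n = 4) to 80.3 ± 6.59 CPM (n = 6), a log2 fold change of -1.14 ± 0.12, and bhlhe40, another repressor, fell by 0.78 ± 0.09. The cryptochrome gene cry2b rose from 238 ± 14.4 to 362 ± 28.9 CPM (0.60 ± 0.08) and nr1d4b rose by 0.78 ± 0.13. The other genes were DNAJA4, a heat shock cochaperone (-1.28 ± 0.20), arhgef9b (-0.57 ± 0.10) and ppp4r4 (-0.53 ± 0.09). Next by p, and not called, were f13a1a.1 (-3.16 ± 0.57), DEDD2 (-0.59 ± 0.11) and ipo8 (-1.58 ± 0.30). Clock genes went both ways, with 8 higher and 9 lower of 42 within the list, and camera did not call the list (adjusted p 0.293). Of 47 interferon-responsive genes 42 lay below 0, with a median of -0.94, and 22 lower and 1 higher ones passed within the list while none passed over all genes. The ubiquitin-like isg15 was at -4.42 ± 0.90 (adjusted p 0.104), parp12a at -1.6 ± 0.38 and stat1a, a transducer of interferon signals, at -0.55 ± 0.14. camera called the list lower (adjusted p 2.68e-19), with estimated-correlation p = 0.109. Mitochondrially encoded mRNAs were all below 0 (median -0.38; 5 of 13 within the list; mt-cyb at -0.47 ± 0.15; estimated-correlation p = 0.308). Lower medians were also called for cytosolic heat shock proteins (-0.15; 5 of 33 within the list; hspa4a at -0.55 ± 0.13; estimated-correlation p = 0.0752) and immediate early genes (-0.23; 3 of 39; atf3 at -0.94 ± 0.21; estimated-correlation p = 0.38). The integrated stress response, glucocorticoid-responsive genes such as ddit4 (-0.66 ± 0.24) and macrophage markers such as marco (-1.24 ± 0.40) were called lower and collagens higher, with estimated-correlation p from 0.485 to 0.835. Complex I subunits had a median of 0.01 and were not called (camera adjusted p 0.751). edgeR called 2 genes higher and 5 lower of 23032, DESeq2 called 121 and voom 134. edgeR called 35 without the treated 3-week brains that stood apart, 3 with the length trend removed (0 higher, 3 lower) and 1 when these groups were fitted alone. Another split of these brains into groups of the same sizes called 126. The count was 3 without control replicate 1, 4 without control replicate 2, 4 without control replicate 4 and 3 without treated replicate 6, and nr1d2b, bhlhe40 and cry2b were called whichever library was left out.

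In liver, 6 fish treated for 8 weeks were compared with 3 controls, and 439 genes were called higher and 1047 lower of 20190. Interferon-responsive genes were among those that fell. Clock genes went both ways, transcripts for hepatocyte plasma proteins and complement stood above other genes, and those of the proteasome, the respiratory chain and cholesterol synthesis below them, though not with an estimated correlation. The clock repressor nr1d1 was at 1.67 ± 0.381 CPM (n = 6) in treated and 30 ± 10.3 CPM (n = 3) in control livers, a fall of 4.16 ± 0.34 on the log2 scale. The genes per1a (-3.84 ± 0.44) and per1b (-2.0 ± 0.28) also fell. Among the genes that rose were nfil3-5 (3.07 ± 0.44), rorcb (2.05 ± 0.39) and cry2b (1.73 ± 0.19). In all, 4 clock genes rose and 13 fell of 41 (10 and 15 within the list), and camera did not call the list (adjusted p 0.149). The clock genes named here and in skin after 8 weeks were chosen after their values were seen, except nfil3-5, per1a and, in skin, nr1d1 and rorcb. Of 49 interferon-responsive genes 24 fell and 0 rose (30 lower and 1 higher within the list). The antiviral GTPase gene mxa was at 1.65 ± 0.587 CPM in treated and 48.3 ± 12.0 CPM in control livers, and mxb (-5.79 ± 0.87), DHX58 (-3.33 ± 0.46) and cmpk2 (-3.13 ± 0.47) fell too. camera called the list lower (adjusted p 7.27e-15), with estimated-correlation p = 0.33.

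Hepatocyte plasma protein genes of the treated livers had a median of 0.55 (5 rose and 1 fell of 45; 7 and 1 within the list). Among them apoea, the gene that fell, was at -9.75 ± 2.09, serpina7 at 1.82 ± 0.39, a2ml at 1.4 ± 0.30 and APOB (3 of 3) at 2.26 ± 0.52. Complement genes had a median of 0.92 (4 rose and 1 fell of 50; 10 and 1 within the list), with c3b at 2.07 ± 0.42, hbl3, the gene that fell, at -7.16 ± 1.53 and c4 at 1.77 ± 0.38. Proteasome genes had a median of -0.60 (9 of 53 fell, 15 within the list, with psmf1, an inhibitor, at -1.43 ± 0.20). camera called these 3 lists, with estimated-correlation p = 0.451 for each. All 39 complex I genes lay below 0 (median -0.40). The median of complexes II to V was -0.33, with cycsb, for cytochrome c and not a subunit, at -1.69 ± 0.40. In each list 1 gene fell, also within the list, with estimated-correlation p = 0.687 for both. Cholesterol synthesis genes had a median of -2.17 (6 of 24 fell; 15 lower and 1 higher within the list), including fdps (-5.84 ± 1.18), lss (-5.59 ± 1.21) and mvd (-5.38 ± 1.31), with estimated-correlation p = 0.695. The p53 target and apoptosis genes bbc3 (-3.32 ± 0.44), btg2 (-2.62 ± 0.47) and baxa (-1.11 ± 0.23) fell with 1 other of 31 (6 within the list; estimated-correlation p = 0.451). Glucocorticoid-responsive genes had a median of -0.69 (4 fell and 1 rose of 18, within the list; estimated-correlation p = 0.451), with pck1 at -2.91 ± 0.63 and the tyrosine catabolism gene tat at 2.17 ± 0.42. Of 62 proliferation genes, 10 fell (11 lower and 1 higher within the list; h2afx at -2.05 ± 0.46 and mcm6 at -3.00 ± 0.73). Of 26 intestine markers 16 fell and 1 rose (21 and 1 within the list; ada at -4.09 ± 0.77 and slc15a1a, a peptide transporter gene, at -6.16 ± 1.18). Both lists had estimated-correlation p = 0.722. Endoplasmic reticulum stress, immediate early, integrated stress response and ribosomal protein lists were called lower, and insulin signalling (ghra at 1.08 ± 0.27), fatty acid oxidation and collagens higher, with estimated-correlation p from 0.501 to 0.793. The called member of the ribosomal list, RPS6KA6, is a kinase of ribosomal protein S6 (0.64 ± 0.17). Fatty acid oxidation genes had a median of 0.16 but a mean of -0.07, with fabp1b.1 at -8.88 ± 1.48, bdh1 at 1.16 ± 0.24 and CPT1A (1 of 2) at 1.06 ± 0.26.

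Part of the liver calls rested on the control with intestine counts. The called genes with the steepest falls, nmrk2, ALPP, mep1a.2, apoea, cd36, chia.3, pdzk1 and ENPP7 (1 of 4), had log2 fold changes from -10.23 to -9.58. Without that library these ran from -2.09 to 2.27 with adjusted p from 0.535 to 0.977. ALPP and ENPP7 (1 of 4) had 3 counts each over the 6 treated livers, so their fold changes depend on the prior count. Without it the medians were 0.91 for intestine markers, 0.33 for proliferation, 0.04 for p53 targets, 0.00 for immediate early genes, 0.16 for hepatocyte plasma proteins and 0.65 for complement. They were -0.14 for fatty acid oxidation (fabp1b.1 at -2.9 and CPT1A (1 of 2) at 0.91, not called), 0.02 for insulin signalling, 0.44 for collagens, -0.78 for the proteasome, -0.57 for complex I, -0.51 for complexes II to V, -0.92 for endoplasmic reticulum stress, -2.69 for cholesterol synthesis and -0.89 for the interferon response. Of these lists camera no longer called the first 4, fatty acid oxidation, insulin signalling and collagens. It newly called lymphocyte markers higher (1.3) and vitellogenin, antioxidant, heat shock, mitochondrial chaperone and gluconeogenesis lists lower. The called member of the complex I list, ndufa4 (-5.50 ± 1.27), a complex IV gene, went to 1.46, while 7 others were then called. Without it hbl3 was at 0.95, slc15a1a at 0.47, ada at -0.35, mcm6 at -1.15 and h2afx at -1.78, and none of them was called. Of the called genes with the steepest rises, kal1a (3.40 ± 0.77), PCBP4 (3.09 ± 0.59) and PRODH (3 of 3) (2.87 ± 0.61) kept their calls without it. The genes tac4 (5.48 ± 1.57), angptl2 (4.24 ± 1.02), aqp9b (3.39 ± 0.95) and actn1 (3.35 ± 0.99) did not, although they stood at 5.61, 3.92, 2.83 and 3.87. Of the 20 named genes that lost their calls 14 left a range of 1.5 times. The count was 925 without this control, replicate 3, of which 565 were among the 1486, and 948 without treated replicate 5. Of the 51 called liver genes named for this comparison, 29 kept their calls whichever library was left out, among them the named clock and interferon genes. edgeR called 471 genes when these groups were fitted alone, DESeq2 2106 and voom 3564.

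In skin, 6 fish treated for 8 weeks were compared with 4 controls, and 672 genes were called higher and 528 lower of 22682. Heat shock and interferon-responsive genes were among those that fell, clock genes went both ways, and lymphocyte, bone and scale genes were among those that rose. The repressor nr1d1 was at 1.33 ± 0.417 CPM (n = 6) in treated and 14.6 ± 7.98 CPM (n = 4) in control skins, a fall of 3.45 ± 0.43 on the log2 scale. per1b (-2.86 ± 0.24), per1a (-2.16 ± 0.42), dbpa (-2.16 ± 0.29) and nr1d2b (-1.53 ± 0.18) fell, and rorcb (1.8 ± 0.41) and cry2b (1.08 ± 0.19) rose. In all, 5 clock genes rose and 11 fell of 42 (10 and 13 within the list), with a median of 0.03, a mean of -0.29 and no camera call (adjusted p 0.194). The small heat shock protein gene hspb11 fell from 52.3 ± 27.3 to 4.83 ± 1.25 CPM (-3.43 ± 0.58). Of 33 cytosolic heat shock genes 16 fell (21 within the list), with hsf2 at -1.0 ± 0.16, hsp90aa1.2 at -1.78 ± 0.34 and hsp90aa1.1 at -3.47 ± 0.67. Of 49 interferon-responsive genes, 19 fell and 1 rose (23 and 2 within the list), with isg15 at -2.97 ± 0.52, DHX58 at -2.19 ± 0.39, mxb at -2.48 ± 0.48 and rsad2 at -2.81 ± 0.54. Muscle genes had a median of -1.57 (2 of 64 fell; 45 within the list), with tnni2b.1 at -2.01 ± 0.49, and their share of counts was 0.842% to 2.89% in treated and 2.05% to 5.77% in control skins. Complex I subunits were all below 0 (median -0.69; 3 of 40 fell; 35 within the list; NDUFB2 at -0.90 ± 0.25). Complexes II to V had a median of -0.64 (1 of 43 fell; 32 within the list; cox6c at -0.85 ± 0.24). The proteasome (-0.39; 2 of 53 fell; 30 within the list), glycolysis (-0.77; 6 of 29; 9; eno1a at -0.86 ± 0.21) and pigment cell genes (-0.45; 7 of 35; 12; slc2a15b at -1.78 ± 0.27, gch2 at -2.43 ± 0.40 and tyr, which encodes tyrosinase, at -1.42 ± 0.26) were lower as well. camera called these 8 lists lower, from heat shock to pigment cells, with adjusted p from 2.89e-17 to 6.31e-06 and estimated-correlation p = 0.391 for each. Whether less muscle accounts for other falls was not tested.

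Of 63 proliferation genes in the treated skins, 9 fell (12 lower and 1 higher within the list), with the replication licensing genes mcm4 (-1.69 ± 0.30), mcm6 (-1.99 ± 0.40) and mcm2 (-2.02 ± 0.42). camera called this list lower, and lymphocyte markers higher (3 of 40 rose; 9 within the list; ikzf1 at 0.91 ± 0.23, PRF1 (1 of 8) at 1.34 ± 0.35 and lck at 0.83 ± 0.22), with estimated-correlation p = 0.604 for both. The bone and scale list was called higher (3 of 32 rose, within the list), with the osteoblast regulators runx2b (1.05 ± 0.26) and runx3 (1.32 ± 0.30) and estimated-correlation p = 0.391. Other lists called lower were mitochondrially encoded mRNAs (median -0.44; mt-nd3 at -0.69 ± 0.20), immediate early genes (nr4a3 at -3.37 ± 0.57), mitochondrial chaperones (lonp1 at -1.0 ± 0.23) and the integrated stress response (slc3a2b at -1.2 ± 0.31). So were glucocorticoid-responsive genes, antioxidant genes (txn at -1.44 ± 0.41), fatty acid oxidation (ucp3 at -2.82 ± 0.52; camera adjusted p 0.0628 without the skins that stood apart) and erythrocyte markers, all of these lists with estimated-correlation p from 0.391 to 0.778. The erythrocyte list held ankrd1a, a stretch-responsive gene of striated muscle and the steepest called fall in skin (-5.30 ± 0.79). It was followed by xirp1, an actin-binding protein of muscle (-4.0 ± 0.48), tph1b, a serotonin synthesis gene (-3.99 ± 1.03), and ppp1r27 (-3.59 ± 0.94). Without control replicate 4 tph1b was at 0.28 and was not called. The steepest rises were those of GZMM (12 of 29), a granzyme (3.33 ± 0.89), loxl2b, a collagen cross-linking enzyme (2.88 ± 0.64), the neutrophil genes mpx (2.27 ± 0.65) and npsn (1.72 ± 0.49), avpr1b (1.89 ± 0.47), blk (1.84 ± 0.43) and the chemokine receptor gene ccr10 (1.78 ± 0.44). Of the 47 called skin genes named for this comparison, 24 kept their calls whichever library was left out, among them nr1d1, per1b, cry2b, hspb11, isg15, tyr and xirp1. The balance of higher and lower calls turned round with these groups fitted alone (777 higher and 977 lower) and without control replicate 1 (243 and 267), but not in 16 other alternatives. With the length trend removed, 831 genes were called higher and 424 lower, DESeq2 called 2368 and voom 4541. The count was 510 without control replicate 1, 376 without control replicate 2, 793 without treated replicate 1, 640 without replicate 3, 705 without replicate 5, and 1804 without the 3-week skins that stood apart.

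**Figure D1:**
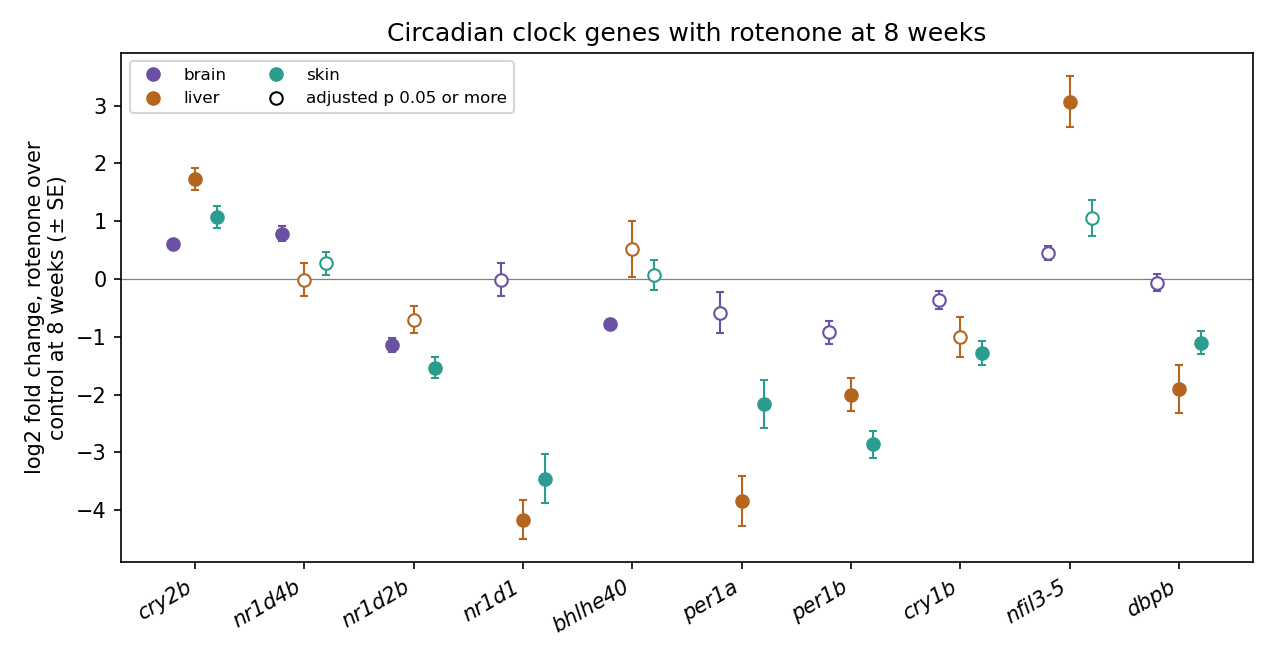
Log2 fold changes (with standard errors) of circadian clock genes between 36-month fish kept in rotenone for 8 weeks and their controls, in brain, liver and skin. nr1d1 was at -4.16 in liver and -3.45 in skin, and cry2b at 0.60 in brain, 1.73 in liver and 1.08 in skin.

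**Figure D2:**
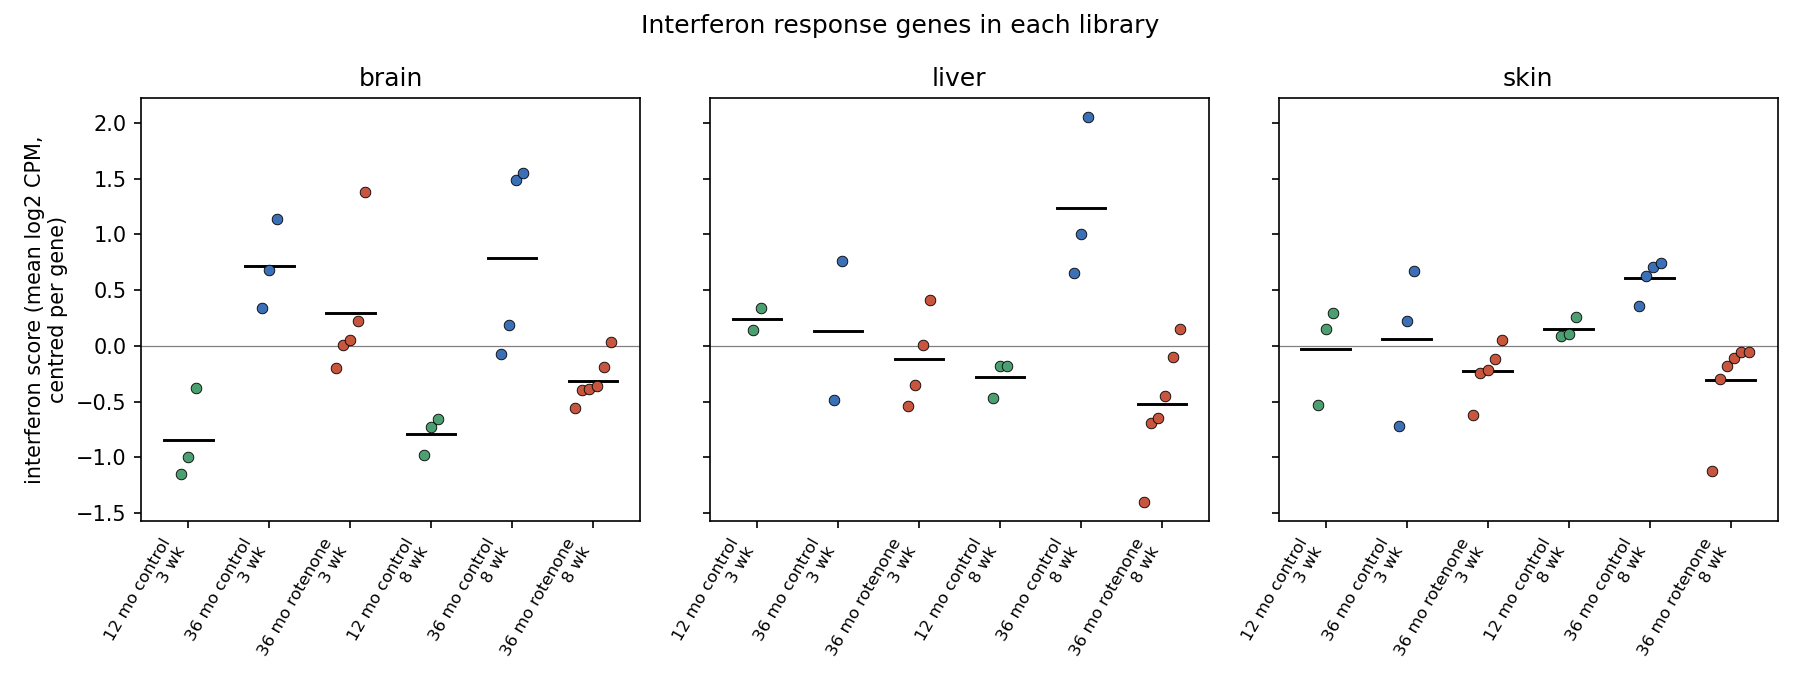
Mean expression score of the interferon response genes in each library, by tissue and group. In 17 of the 18 rotenone libraries (6 fish) at 8 weeks the score lay below every 36-month control library of the tissue and time.

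The fish-level interferon means followed the gene-level counts after 8 weeks. In liver 6 of 6 treated fish lay below every 36-month control of that time (difference -1.76, exact permutation p = 0.0119, the smallest that 84 splits can give, adjusted p 0.0857 over the lists of the tissue). In skin this held for 6 of 6 (-0.92, exact permutation p = 0.00476, the smallest that 210 splits can give, adjusted 0.054) and in brain for 5 of 6 (-1.1, exact permutation p = 0.00952, adjusted 0.167). For complex I the fish-level differences were 0.06 in brain (exact permutation p = 0.471), -0.38 in liver (0.0595) and -0.65 in skin (0.0143, adjusted 0.054).

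**Figure D3:**
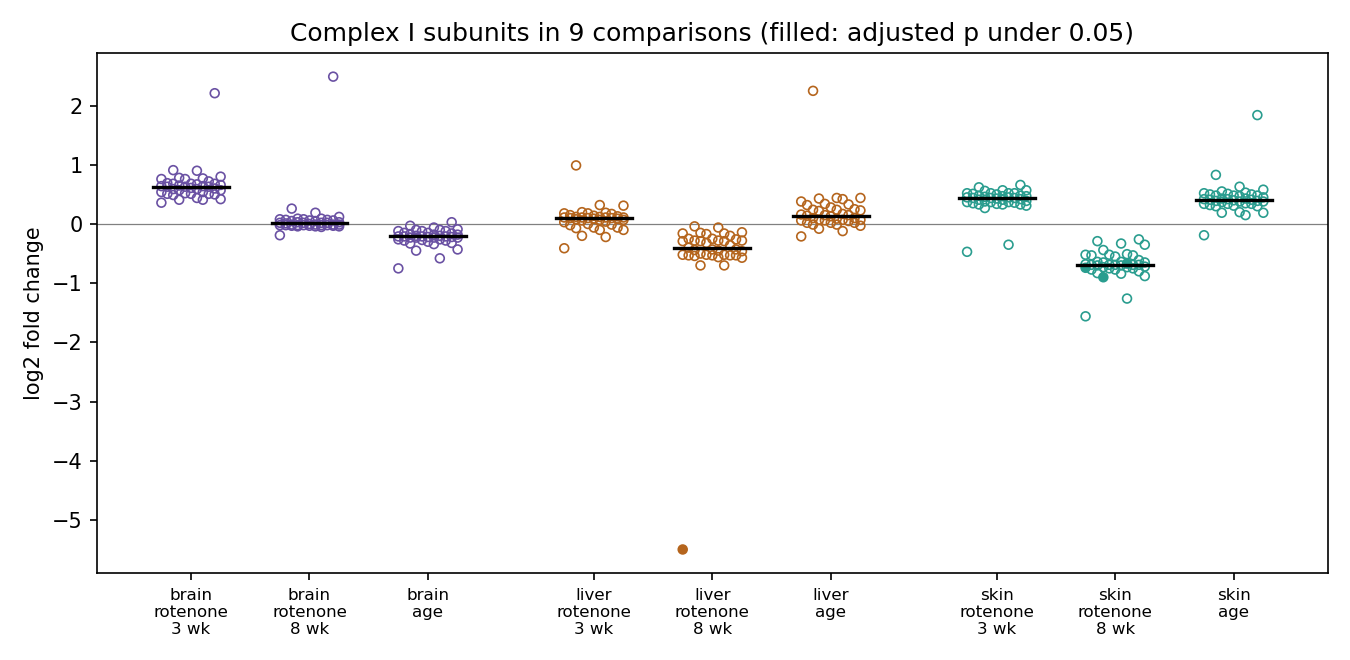
Log2 fold changes of complex I subunits with rotenone and with age in each tissue. The medians with rotenone were 0.63, 0.10 and 0.44 after 3 weeks and 0.01, -0.40 and -0.69 after 8 weeks in brain, liver and skin.

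Whether the response differed between 8 and 3 weeks was tested as an interaction. In liver 14 genes were called, among them the clock repressors nr1d1 (-4.58, adjusted p 0.0131) and nr1d2a (-4.04, adjusted p 0.0371) and per1a (-4.50, adjusted p 0.0371), which lay lower after 8 weeks relative to 3. The receptor genes rxraa (-2.67, adjusted p 0.0371) and lrp1 (2.87, adjusted p 0.0323) and the iron-sensing TFR2 (2 of 2) (2.77, adjusted p 0.0371) also differed, and none of these 6 kept its call whichever library was left out. The liver count was 46 and 0 without 3-week control replicates 1 and 2, 2, 4 and 60 without 8-week control replicates 1, 2 and 3. It was 2, 4, 30 and 2 without 3-week treated replicates 1, 2, 3 and 4, and 9 and 3 without 8-week treated replicates 2 and 5. In brain edgeR called 0 genes (1781 at an unadjusted p under 0.05; DESeq2 11; voom 5), and 1 without 8-week control replicate 3 or 8-week treated replicate 5. In skin edgeR called 0 genes (2410 at an unadjusted p under 0.05; DESeq2 90 higher and 97 lower; voom 1). It called 5, 27 and 4 without 3-week control replicates 1, 2 and 3, and 16 without 8-week control replicate 1. It called 1, 5, 7 and 13 without 3-week treated replicates 1, 2, 3 and 4, and 1 without 8-week treated replicate 6.

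Control brains of 36 months were compared with those of 12 months, averaged over both times (7 and 6 fish). Interferon and lymphocyte genes were among those that rose in old brains, and 323 genes were called higher and 132 lower. Of 47 interferon-responsive genes 22 rose (40 higher and 1 lower within the list; median 1.6), among them mxb (5.63 ± 1.24), isg15 (4.1 ± 0.86), si:ch211-219a4.3 (1.77 ± 0.28), the antigen presentation genes b2m (1.24 ± 0.21) and tapbp (1.24 ± 0.24), and irf9 (0.97 ± 0.17). isg15 was at 44.4 ± 44.2 CPM and 67.5 ± 66.3 CPM in old and at 1.75 ± 1.07 CPM and 5.83 ± 2.65 CPM in young brains at 3 and 8 weeks. camera called the list (adjusted p 4.17e-28), with estimated-correlation p = 0.0523. Lymphocyte markers rose in 8 of 37 cases (16 within the list), with the T cell genes il7r (2.04 ± 0.32), itk (2.29 ± 0.38) and cd4 (1.71 ± 0.34) and estimated-correlation p = 0.169. Of 40 macrophage and microglia markers 4 rose and 1 fell (10 and 1 within the list), with CD68 at 1.07 ± 0.20, marco at 1.75 ± 0.37, c1qa at 0.99 ± 0.22 and slc7a7 at -0.80 ± 0.18, and estimated-correlation p = 0.225. Lower in old brains were immediate early genes (2 of 39 fell; 14 lower and 1 higher within the list; dusp4 at -0.63 ± 0.14 and klf4 at -1.03 ± 0.26; estimated-correlation p = 0.169). Lower too were proliferation genes (2 of 64 fell; 3 within the list; RRM2 (1 of 2) at -1.55 ± 0.25 and rrm2 at -0.94 ± 0.18; estimated-correlation p = 0.473). Cholesterol synthesis genes (25 of 26 below 0; 0 within the list) and myelin genes (plp1a at -0.42 ± 0.12, omga at -0.46 ± 0.14; 5 of 24 within the list) were called lower with estimated-correlation p = 0.473 for both. Nuclear-encoded respiratory chain lists were lower (complex I median -0.21, with 39 of 40 below 0, and complexes II to V -0.23) and mitochondrially encoded mRNAs higher (0.20), with estimated-correlation p from 0.58 to 0.68. Fatty acid synthesis, radial glia genes, dopaminergic neuron genes (nr4a2b at -0.60 ± 0.11), collagens and synaptic genes (nefm, a neurofilament gene, at -1.67 ± 0.41; camera adjusted p 0.0542 without the brains that stood apart) were called lower, with estimated-correlation p from 0.225 to 0.68.

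The other steepest rises in old brains were NLRX1 (51 of 54), serpinb1l2, gzma, SHISA5 (2 of 2) and IL4I1, with log2 fold changes from 4.0 to 4.96. The steepest falls were iqch (-2.59 ± 0.46), wnt4b (-2.14 ± 0.37), PLXDC2 (2 of 2) (-1.97 ± 0.22), ern1, a sensor of unfolded proteins in the endoplasmic reticulum (-1.45 ± 0.18), bhik and matn4. ern1 was at 28.7 ± 4.38 and 26.8 ± 2.48 CPM in old and 65.5 ± 30 and 87.6 ± 4.4 CPM in young brains. Of the 30 called brain genes named for age, 15 kept their calls whichever library was left out, including ern1, b2m, irf9, il7r and CD68, while isg15 and mxb did not. At 3 weeks alone 7 genes differed with age, including cry2b (0.78, adjusted p 0.00302) and il7r (2.64, adjusted p 0.0493). At 8 weeks alone 28 differed, including ern1 (-1.71, adjusted p 0.00388) and CASKIN2 (3 of 4) (-1.49, adjusted p 0.00388). The pooled test called 126 genes higher and 60 lower without 12-month replicate 1 at 3 weeks, and 235 in all without replicate 2. Without 12-month replicates 1 and 2 at 8 weeks it called 139 higher and 66 lower, and 129 higher and 54 lower. The count was 236 without 12-month replicate 3 at 8 weeks, 270 without 36-month replicate 3 at 3 weeks, and 843 without the rotenone brains that stood apart. The 3-week count was 1 and 17 without 12-month replicates 1 and 3 and 26 and 0 without 36-month replicates 1 and 3. The 8-week count was 7, 7 and 6 without 12-month replicates 1, 2 and 3 and 13, 8, 13 and 9 without 36-month replicates 1, 2, 3 and 4.

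In control livers 5 fish of 36 months were compared with 5 of 12 months, and 101 genes were called higher and 86 lower. DESeq2 called 1087, voom 103 and edgeR 0 with these groups fitted alone (2657 at an unadjusted p under 0.05). Genes of glucocorticoid response and glucose production stood below other genes in old livers, but not with an estimated correlation. The bloodthirsty-related genes btr29 (4.98 ± 0.79), btr18 (4.11 ± 0.60), btr24 (3.90 ± 0.54) and ftr54, of a related family (3.48 ± 0.77), rose. So did ODZ2 (2 of 3) (8.93 ± 1.35), ST3GAL1 (5 of 5) (6.99 ± 1.53), NLRX1 (36 of 54) (3.37 ± 0.55) and the receptor gene ret (3.17 ± 0.60). Of 18 glucocorticoid-responsive genes sgk1 (-2.27 ± 0.40) and pck1 (-3.24 ± 0.66) fell (6 within the list; median -0.81; estimated-correlation p = 0.138). pck1 was at 64.3 ± 30.5 CPM in old and 3700 ± 652 CPM in young livers at 3 weeks, and at 1120 ± 328 and 1740 ± 738 CPM at 8 weeks. Clock genes nr1d1 (-1.66 ± 0.32) and nfil3-6 (-1.57 ± 0.30) fell and arntl1b, a partner of CLOCK, rose (0.83 ± 0.19). C25H1orf51 (2 of 2) fell (-0.77 ± 0.16), making 1 higher and 4 lower of 41 (3 and 6 within the list; estimated-correlation p = 0.692). Of the interferon-responsive genes 2 of 49 rose, BX000534.2 and BX000534.1 (20 higher and 1 lower within the list; median 0.65, or 0.25 without the control with intestine counts; estimated-correlation p = 0.692). Ribosomal proteins (median 0.38; rplp1 at 0.83 ± 0.22), pancreas markers (3.48; CELA1 (3 of 7) at 2.35 ± 0.81), complexes II to V (0.29), the proteasome (0.22) and endoplasmic reticulum stress genes (0.58, although ern1 in it fell by 1.18 ± 0.14) were called higher. Their estimated-correlation p ran from 0.692 to 0.907, with none but ern1 past the threshold within the list. Gluconeogenesis genes (-0.35; 3 of 47 within the list), immediate early genes (-0.47; csrnp1b at -1.69 ± 0.36, jund at -1.23 ± 0.28), fatty acid synthesis (-0.33; lpin1 at -2.50 ± 0.60), complement, fatty acid oxidation, neutrophil markers (-1.02; mmp9 at -3.06 ± 0.92), mitochondrially encoded mRNAs and insulin signalling were called lower, with estimated-correlation p from 0.419 to 0.84. Without the control with intestine counts the medians were -0.28 for the clock (-0.09 with it), -0.82 for immediate early genes, -0.22 for gluconeogenesis and -0.2 for complement, and fatty acid oxidation and insulin signalling were not called. Newly called then were 5 lists. With all libraries complex I had a median of 0.14 and was not called (camera adjusted p 0.133).

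The other steepest falls in old livers were mybpc1 (-4.75 ± 1.04), gli3 (-3.85 ± 0.87), FAT2 (-3.47 ± 0.61), mfsd2ab, a lipid transporter (-3.10 ± 0.51), snrk1 (-2.93 ± 0.44), plxnc1 and tdh. Of the 26 called liver genes named for age, 2 (ern1 and snrk1) kept their calls whichever library was left out. The median of all genes lay at 0.12, or 0.11 at 3 weeks alone, so the fold changes stand relative to that shift, and with the length trend removed 84 genes were called higher and 108 lower. At 3 weeks alone 5 genes rose (LIG3, SMUG1, znf142, zgc:153845 and zgc:153292) and at 8 weeks alone 19 differed, with ern1 at -1.56 (adjusted p 0.00197). The pooled count was 27 and 12 without 12-month replicates 1 and 2 at 3 weeks, and 63, 60 and 92 without 12-month replicates 1, 2 and 3 at 8 weeks. It was 92, 76 and 311 without 36-month replicates 1, 2 and 3 at 8 weeks. The 3-week count was 0 and 1 without 12-month replicates 1 and 2, and 145 and 79 without 36-month replicates 1 and 2. The 8-week count was 1, 1 and 5 without 12-month replicates 1, 2 and 3, and 117 and 1 without 36-month replicates 1 and 2.

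In control skins 7 fish of 36 months were compared with 6 of 12 months, and 260 genes were called higher and 286 lower. Keratinocyte, ribosomal and chaperone genes were among those that rose in old skins, and the elongase gene elovl5 fell. Of 53 keratinocyte genes 9 rose (18 within the list; median 0.43), among them krt17 (0.91 ± 0.12), anxa1b (1.37 ± 0.25) and krt18 (1.21 ± 0.27). krt17 was at 846 CPM (720 to 1060) in old and 249 ± 16.1 CPM in young skins at 3 weeks, and at 211 ± 40.9 CPM in old and 192 to 218 CPM in young skins at 8 weeks. Ribosomal proteins had a median of 0.34 (4 of 87 rose; 80 within the list; rplp1 at 0.63 ± 0.14, rps12 at 0.50 ± 0.11) and the proteasome 0.33 (1 of 53; 25; psma2 at 0.47 ± 0.11). Mitochondrial chaperones had a median of 0.41 (3 of 19; 14; lonp1 at 0.88 ± 0.20, hspe1 at 0.85 ± 0.20), heat shock genes 0.66 (5 of 33; 17 higher and 1 lower; stip1 at 0.54 ± 0.12, hspa4a at 1.13 ± 0.28) and mitochondrially encoded mRNAs 0.47 (0 of 13; 12), the second counts being within the list. camera called these 6 lists higher, with estimated-correlation p = 0.382 for each. Complex I (median 0.41) and complexes II to V (0.44; uqcrc2a at 0.76 ± 0.19) were called higher and cholesterol synthesis lower (-0.72; scap at -1.07 ± 0.37), with estimated-correlation p = 0.423 for each. Clock genes were lower (35 of 42 below 0; cry2b rose by 0.86 ± 0.16 and dbpb fell by 0.69 ± 0.17; 1 higher and 4 lower within the list). So were fatty acid synthesis genes (elovl5 at -0.86 ± 0.12, dgat1b at -0.54 ± 0.14 and elovl1b at 0.40 ± 0.10; 7 lower and 1 higher of 27 within the list), with estimated-correlation p = 0.382 for both. Muscle genes (median 0.95, or 0.23 without the libraries with testis genes), the interferon response, proliferation, endoplasmic reticulum stress, glycolysis (hk2 at 0.96 ± 0.17), the integrated stress response (mthfd1l at 2.04 ± 0.34) and erythrocyte markers were called higher. Collagens (col17a1b at 1.16 ± 0.26, loxl2a at 0.92 ± 0.24 and col1a2 at -2.08 ± 0.55), bone and scale genes, glucocorticoid-responsive genes and insulin signalling were called lower, all of these with estimated-correlation p from 0.382 to 0.601. Without the libraries with testis genes the medians were 0.30 for heat shock genes, 0.26 for complex I, 0.28 for complexes II to V, 0.70 for proliferation (0.17 with them), -0.26 for fatty acid synthesis (-0.05) and 0.07 for the integrated stress response (0.12). Muscle, endoplasmic reticulum stress (0.12) and erythrocyte genes (0.07) were then not called.

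The other steepest rises in old skins were NLRX1 (51 of 54) (3.64 ± 0.95), the heat shock cochaperone gene ahsa1 (3.54 ± 0.91), ankrd1a (2.60 ± 0.65), GZMM (6 of 29), AARSD1, pvalb7 and btr29. The steepest falls were fgfr1bl (-4.35 ± 1.16), the coagulation factor gene f2 (-3.54 ± 0.74), btr21, plekhs1, HPX (1 of 2), NAGS (-3.25 ± 0.59), PFKFB1 (1 of 2) and fynrk. Without the skins with testis genes, mthfd1l, btr29, f2, HPX (1 of 2), NAGS, PFKFB1 (1 of 2), hk2, krt17 and elovl5 were still called. Of the 25 named genes that lost their calls, only uqcrc2a (0.50), AARSD1 (1.2) and pvalb7 (1.23) left a range of 1.5 times. Others were ahsa1 (2.37), ankrd1a (2.14), fgfr1bl (-3.82), loxl2a (0.95), col1a2 (-2.05), rplp1 (0.62), psma2 (0.47) and stip1 (0.51). Of the 36 called skin genes named for age, 6 (mthfd1l, anxa1b, elovl5, krt17, hk2 and NAGS) kept their calls whichever library was left out. Without the 12-month replicate 1 at 3 weeks f2 was at -1.43 and HPX (1 of 2) at -0.01, and neither was called. The pooled count was 42 with these groups fitted alone and 213 without the skins with testis genes, and another split of these skins into groups of the same sizes called 1787. It was 56, 950 and 320 without 12-month replicates 1, 2 and 3 at 3 weeks, and 148, 60 and 108 without 12-month replicates 1, 2 and 3 at 8 weeks. It was 1641 without 36-month replicate 1 at 3 weeks and 347 without 36-month replicate 1 at 8 weeks. Without 36-month replicate 3 at 3 weeks 90 genes were called higher and 68 lower, and without replicates 2 and 4 at 8 weeks 100 higher and 105 lower, and 85 higher and 102 lower. At 3 weeks alone 82 genes differed, with krt17 at 1.77 (adjusted p 6.56e-05), and at 8 weeks alone 5, with CASKIN2 (3 of 4) at -2.38 (adjusted p 5.89e-05). The 3-week count was 12, 347 and 280 without 12-month replicates 1, 2 and 3, and 737 and 7 without 36-month replicates 1 and 3, and the 8-week count 11 and 3 without 36-month replicates 3 and 4.

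Controls sampled at 8 weeks were also compared with those at 3 weeks, over both ages. With these groups fitted alone edgeR called 26 genes in brain, 0 in liver (3569 at an unadjusted p under 0.05; DESeq2 with all groups 2478, voom 1968) and 61 in skin. With all groups, in brain 4 genes were higher and 24 lower, and 14 of these 28 were clock genes, among them cry5 (-1.33 ± 0.12), nr1d2b (-0.93 ± 0.11), per1b (-1.18 ± 0.17), per2 (-0.60 ± 0.09) and nfil3-5 (0.92 ± 0.11). In liver 732 genes were higher and 751 lower, with 14 clock genes among them (nr1d2a at 2.2 ± 0.40, clock at 2.01 ± 0.38). In skin 251 were higher and 488 lower, with 10 clock genes (clock at 1.25 ± 0.22, dbpa at -1.19 ± 0.25). Of 41 clock genes measured in the 3 tissues, 17 went the same way in all of them, against 29 of 41 with rotenone at 8 weeks. The brain count was 18, 16 and 44 without 12-month replicate 2 at 3 weeks, 12-month replicate 2 at 8 weeks and 36-month replicate 2 at 3 weeks. Another split of the control livers by time called 2768 genes. The liver count was 291 and 708 without 12-month replicates 1 and 2 at 3 weeks, and 751 and 887 without 12-month replicates 1 and 3 at 8 weeks. It was 2571 and 142 without 36-month replicates 1 and 2 at 3 weeks and 970, 928 and 2327 without 36-month replicates 1, 2 and 3 at 8 weeks. The skin count was 470, 468 and 1125 without 12-month replicates 1, 2 and 3 at 3 weeks, and 275, 180 and 155 without 12-month replicates 1, 2 and 3 at 8 weeks. It was 1601 and 266 without 36-month replicates 2 and 3 at 3 weeks, and 357 and 368 without 36-month replicates 1 and 2 at 8 weeks.

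Tissue differences in the rotenone response at 8 weeks and the age effect were tested in a fit of all libraries. Between brain and liver, 1419 genes differed in their rotenone response (629 with fish as a block), including nr1d1 (4.1 ± 0.53, higher in brain), PCBP4 (-3.12 ± 0.44) and the intestinal transporter gene slc6a19a (7.16 ± 1.01). Between brain and skin 18 genes differed (9 with fish as a block), including nr1d1 (3.45 ± 0.52), per1b (1.95 ± 0.34) and ankrd1a (5.17 ± 0.92). Between liver and skin 1386 differed (605 with fish as a block), including tmcc3 (-2.13 ± 0.21), srgap1 (2.29 ± 0.26) and lrp1 (2.53 ± 0.37). Without the fish whose control liver held intestine counts the counts were 571, 4 and 424. For age, 428 genes differed between brain and liver (245 with fish as a block; ODZ2 (2 of 3) at -8.88 ± 0.93, ret at -3.81 ± 0.49). Between brain and skin 58 differed (94 with fish as a block; lgals3bpa at 2.71 ± 0.47, btr26 at 2.39 ± 0.45) and between liver and skin 453 (260 with fish as a block; MREG at 5.50 ± 0.57, gli3 at -4.0 ± 0.64). Of 24 splits by age some others called more, up to 120 genes between brain and skin and 545 between liver and skin.

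Correlations across genes asked whether rotenone moved genes the way age does, with no library shared between the 2 sides, and whether it moved them alike in different tissues. Genes are not independent replicates, so the labels of the fish were permuted, and p was adjusted over the 9 correlations. Between rotenone at 8 weeks and age at 3 weeks r was -0.201 in brain (permutation p = 0.0905, adjusted 0.407), 0.002 in liver (0.976, adjusted 0.976) and -0.105 in skin (0.438, adjusted 0.6). Between rotenone at 3 weeks and age at 8 weeks it was -0.126 in brain (permutation p = 0.286, adjusted 0.6), -0.101 in liver (0.467, adjusted 0.6, where 15 splits cannot give a p under 0.067) and -0.072 in skin (0.696, adjusted 0.783). The responses at 8 weeks correlated between brain and liver with r = 0.385 (permutation p = 0.0119, the smallest that 84 splits can give, adjusted 0.107), but the next split reached 0.381. Without each of the 3 control fish with both tissues in turn, p was 0.25, 0.107 and 0.0714. Between brain and skin r was 0.328 (permutation p = 0.386, adjusted 0.6) and between liver and skin 0.356 (0.274, adjusted 0.6).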

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

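The tests of clock, intestine, cholesterol, proliferation and interferon genes, and the other splits of brain libraries for rotenone, were chosen after the results were seen. Within groups of 4 to 6 libraries, 45 comparisons were made for a library far from the rest, 7 met the limit, and chance gives about 1 in 20. Rotenone replicate 5 of the 8-week brains had total counts of 54.9 M against 28 to 37.5 M in the others, and replicate 3 had 0.444% of its counts in pituitary hormone genes (others 0.0772% to 0.113%). Replicate 6 of the 8-week rotenone livers had 7.62% in pancreas markers (others 0.0295% to 1.41%), and replicate 4 had nr1d1 at 0.943 CPM (others 1.64 to 2). Replicate 3 of the 36-month control skins at 8 weeks had 0.0245% in testis and germ cell genes (others 0.00196% to 0.00282%). The interferon score, the mean of the interferon genes, was 1.38 in replicate 1 of the 3-week rotenone brains (others -0.2 to 0.22) and -1.12 in replicate 6 of the 8-week rotenone skins (others -0.3 to -0.06).

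Tested directly, rotenone responses at 8 weeks differed for 1419 genes between brain and liver and 18, with muscle genes among them, between brain and skin. Between liver and skin 1386 did. Only 24 of 84 splits of the fish were fitted for rotenone and 24 of 240 for age, so chance is judged among those. The 3 rotenone counts lay above those of every other split drawn, of which the highest called 1162, 15 and 953. Without the fish whose control liver held intestine counts the real counts were 571, 4 and 424, below those values. For age 428 genes differed between brain and liver (highest other split 397). That count was 245 with fish as a block and varied without single fish. With so few splits and this margin, chance is not excluded. Nor is it for the 58 between brain and skin (highest other 120) or the 453 between liver and skin (highest other 545). In liver 14 genes differed between the rotenone responses at 8 and 3 weeks. That count was not set against other splits, since the 3-week controls were 2 fish.

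Within tissues up to 100 splits were fitted (100 of 210 for rotenone at 8 weeks in brain and skin, and 100 of 700 for pooled age and control time there). Among those fitted, counts argue against chance for rotenone at 8 weeks in skin (1200 genes, highest other split 28). In brain they do for pooled age (455, 64), age at 8 weeks (28, 0) and control time (28, 6). Chance stays open for rotenone at 8 weeks in brain (7, 126) and liver (1486, 971, but 925 without the control with intestine counts). It also does for pooled age in skin (546, 1787) and liver (101 higher and 86 lower, 84, down to 12 without single libraries). Fitted alone, liver age gave 0 (2657 at an unadjusted p under 0.05, DESeq2 1087, voom 103). Chance stays open too for age at 8 weeks in skin (5, 2) and control time in liver (1483, 2768, down to 142) and skin (739, 632, down to 155). Fitted alone, control time gave 0 in liver (3569 at an unadjusted p under 0.05, DESeq2 2478, voom 1968) and 61 in skin. Where edgeR called 0 genes the splits cannot test the count, since every split calls at least as many. These are rotenone at 3 weeks in brain (0, 5947; 2941 genes at an unadjusted p under 0.05, DESeq2 35, voom with quality weights 0) and skin (0, 487; 2281, DESeq2 96, voom 0). They are also the difference between times (40 of 11760 splits) in brain (0, 1; 1781, DESeq2 11, voom 5) and skin (0, 220; 2410, DESeq2 90 higher and 97 lower, voom 1). Splits into 3 and 3 libraries are too few for a share under 0.05 (brain, age at 3 weeks: 7, highest other 0; skin, age at 3 weeks: 82, 1721; liver, age at 8 weeks: 19, 1). Splits that call several times the real count, as in brain for rotenone at 8 weeks and in skin for pooled age, may point to sample structure other than the groups.

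Clock genes changed in all 3 tissues after 8 weeks of rotenone. Removing the trend of counts over transcript length left 35 of 37 clock calls in the same direction, although in brain the rises of cry2b (0.61) and nr1d4b (0.79), 2 of 4 calls, were lost (adjusted p 0.0598 and 0.0807). This argues against that trend as the whole cause. At least 10 clock genes per tissue also differed between untreated controls of the 3-week and 8-week samplings, so a difference in the hour of sampling may account for the changes. The hours are not given in the sources used here, so this and an effect of rotenone on the clock cannot be told apart.

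Intestinal tissue in 1 control liver library may account for the fall of intestine markers with rotenone at 8 weeks, whose median log2 fold change was 0.91 without that library, and for that of proliferation genes (-1.02 with it, 0.33 without). It does not account for lower cholesterol synthesis genes, at -2.17 with and -2.69 without that library. An effect of rotenone on cholesterol synthesis stays open, since the list was not called with an estimated correlation.

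In 17 of 18 rotenone libraries (6 fish) at 8 weeks, interferon genes were lower than in every 36-month control of their tissue and time. At least 15 such genes were called lower in liver and in skin whichever control library was left out, which argues against 1 control fish with high values as the cause. Fewer lymphocytes and macrophages would lower both immune cell lists, but the lower of their medians was 0.06 in skin and 0.61 in liver without the library with intestine counts, while -0.14 in brain leaves this open there. The exact permutation p was 0.00952, 0.0119 and 0.00476 in brain, liver and skin, the last 2 being the smallest possible. The tissues share fish, so these p are not independent. At these numbers of splits no list could pass when adjusted unless at least 4 of 35, 9 of 36 and 4 of 34 passed together, so the adjusted 0.167, 0.0857 and 0.054 do not speak for chance. The list was chosen after the results were seen, so chance differences between the fish and an effect of rotenone both stay open. The number of tanks is not given, so a difference between tanks cannot be told apart from an effect of rotenone.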

How the results depend on the processing

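Fits without the 5 libraries that stood apart and with the length trend removed were chosen after the data were seen, the others beforehand. In the order rotenone at 3 weeks, rotenone at 8 weeks, their difference, pooled age, age at 3 weeks, age at 8 weeks and control time, edgeR called 0, 7, 0, 455, 7, 28 and 28 genes in brain. In liver it called 0, 1486, 14, 101 higher and 86 lower, 5, 19 and 1483, and in skin 0, 1200, 0, 546, 82, 5 and 739. With RLE size factors the counts were 0, 5, 0, 453, 6, 28 and 24, then 0, 1572, 14, 200, 5, 11 and 1469, then 0, 1147, 0, 554, 81, 5 and 751. Without the filter on low counts, where more genes were tested, they were 0, 5, 0, 400, 6, 32 and 23, then 0, 1221, 13, 77, 0, 1 and 1000, then 0, 881, 0, 311, 18, 5 and 514. DESeq2 gave 35, 121, 11, 985, 223, 356 and 77, then 27, 2106, 393, 1087, 574, 640 and 2478, then 96, 2368, 1.9e2 (90 higher and 97 lower), 1724, 848, 163 and 1421. Voom with quality weights gave 0, 134, 5, 1969, 245, 1195 and 192, then 0, 3564, 9, 103, 0, 746 and 1968, then 0, 4541, 1, 899, 1, 1583 and 479. With the groups of a contrast fitted alone, and so with fewer samples, the counts were 0, 1, 0, 905, 1, 131 and 26, then 0, 471, 2, 0, 0, 3 and 0, then 0, 1754, 0, 42, 0, 34 and 61. Without the libraries that stood apart they were 0, 35, 0, 843, 84, 92 and 45, then 0, 925, 60, 311, 91, 21 and 2327, then 0, 1804, 4, 213, 3, 42 and 257. With the length trend removed they were 1, 3, 0, 413, 2, 17 and 24, then 0, 1548, 16, 192, 6, 9 and 1441, then 0, 1255, 16, 398, 94, 19 and 787. Leaving out each library gave 0 to 6, 3 to 9, 0 to 1, 1.8e2 (129 higher and 54 lower) to 433, 0 to 26, 6 to 13 and 16 to 44 in brain. It gave 0 to 21, 925 to 1560, 0 to 60, 12 to 311, 0 to 145, 1 to 117 and 142 to 2571 in liver, and 0 to 320, 376 to 1357, 0 to 27, 56 to 1641, 7 to 737, 3 to 11 and 155 to 1601 in skin. Where a count left its range of 1.5 times and neither more genes nor fewer samples account for it, the cause was not tested.

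Replicate numbers are shared between groups but do not pair the fish: same-numbered libraries of different groups had a median correlation of -0.002, 0.002 and -0.011 in brain, liver and skin, against -0.006, 0.006 and 0.011 for other numbers. With the number as a block the counts were 0, 2, 0, 297, 31, 19 and 16 in brain, 0, 21, 0, 23, 0, 0 and 145 in liver, and 0, 668, 0, 165, 5, 4 and 189 in skin.

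Between tissues, in the order brain-liver, brain-skin and liver-skin for rotenone and then for age, 1419, 18, 1386, 428, 58 and 453 genes differed. With fish as a block these were 629, 9, 605, 245, 94 and 260, with DESeq2 1886, 118, 1923, 1115, 357 and 996, and without the libraries that stood apart 1153, 52, 858, 1197, 132 and 684. Leaving out each fish gave 571 to 1551, 4 to 21, 424 to 1572, 176 to 705, 8 to 81 and 191 to 555.

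Correlations near 0 changed sign, and ranges are those over fits without each library or fish. By rank, and over genes with a mean CPM of at least 10, that of rotenone at 8 weeks and age at 3 weeks was -0.076 and -0.213 in brain, -0.009 and 0.016 in liver and -0.137 and -0.216 in skin. That of rotenone at 3 weeks and age at 8 weeks was -0.139 and -0.204, -0.087 and -0.2, and -0.068 and -0.027. Between brain and liver it was 0.283 and 0.445, brain and skin 0.266 and 0.388, and liver and skin 0.326 and 0.456. That of rotenone at 8 weeks and age at 3 weeks in liver was -0.09 without the control with intestine counts, and also below 0 without other libraries (-0.018, -0.079, -0.005, -0.045; range -0.09 to 0.073). In skin it ranged from -0.181 to 0.027, and was -0.153 without control replicate 1 at 3 weeks (permutation p = 0.0381). In brain it ranged from -0.241, without control replicate 3 at 3 weeks (permutation p = 0.0476), to -0.137. That of rotenone at 3 weeks and age at 8 weeks ranged from -0.213 to 0.033 in liver, -0.168 to 0.085 in skin, where it was 0.085 without the libraries that stood apart and 0.01 without a further control, and -0.164 to -0.086 in brain. Between tissues the ranges were 0.297 to 0.386 for brain and liver (0.372, 0.297 and 0.32 without single control fish, permutation p 0.0714, 0.25 and 0.107), 0.263 to 0.382 for brain and skin, and 0.266 to 0.415 for liver and skin.

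Of 301 named values, 224 were past the threshold. Signs changed in liver after 8 weeks of rotenone without the control with intestine counts. Over the fits without each library the log2 fold changes ran from -6.82 to 0.47 for slc15a1a, -7.85 to 0.95 for hbl3, -10.49 to 2.27 for ENPP7 (1 of 4), -10.67 to 0.15 for mep1a.2, -6.16 to 1.46 for ndufa4, -10.25 to 0.58 for pdzk1, -10.89 to 1.79 for nmrk2 and -10.4 to 0.22 for cd36, each highest without that control. With quality weights slc15a1a was at 0.45, hbl3 at 0.51, ENPP7 (1 of 4) at 0.03, chia.3 at 1.57, ndufa4 at 0.83, pdzk1 at 0.50 and nmrk2 at 0.77. In skin tph1b was at 1.26 with quality weights and from -4.41 to 0.28, the latter without control replicate 4. Of all gene lists called with the preset correlation, 40 had fewer calls with an estimated one, 0 in each case but the glucocorticoid list, which had 1. With the length trend removed the median of all genes lay at 0.131 for age at 8 weeks in liver and 0.114 for the rotenone difference in skin. The split of higher and lower calls moved to 2 and 3 (brain, rotenone at 8 weeks), 4 and 1 (liver, age at 3 weeks) and 5 and 6 (liver, age at 8 weeks) with RLE factors. With the length trend removed it was 0 and 2 (brain, age at 3 weeks), 9 and 8 (brain, age at 8 weeks), 5 and 4 (liver, age at 8 weeks) and 5 and 14 (skin, age at 8 weeks). The larger of the higher and lower calls became the smaller in 7 of 14 alternatives for age at 3 weeks and 3 of 15 for age at 8 weeks in brain. In liver it did so in 12 of 18 for pooled age, 9 of 14 for age at 8 weeks and 12 of 18 for control time. In skin it did so in 2 of 18 for rotenone at 8 weeks, 6 of 21 for pooled age, 5 of 14 for age at 3 weeks and 1 of 21 for control time. Between tissues, in the order above, it did so in 1, 0 and 2 of 15 for rotenone and in 1, 0 and 4 of 18 for age. Without the libraries that stood apart, camera lost and gained 3 and 3, 0 and 3, and 1 and 0 lists in brain (rotenone at 3 and 8 weeks, pooled age), 0 and 1, 7 and 6, and 2 and 5 in liver, and 1 and 9, 1 and 0, and 3 and 2 in skin. Where leaving out a library left 1 fish in a group, that fish was assumed to vary like those of the other groups.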

Other observations

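After 8 weeks of rotenone 226 genes were called in both liver and skin. Of these 66 rose and 146 fell in both and 14 went opposite ways. Independent calls would put 36.6 in the same direction. The tissues come from the same fish, so these calls are not independent.

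With age, or cohort, 6 genes were called in all 3 tissues. The gene ern1 fell in brain (-1.45 ± 0.18), liver (-1.18 ± 0.14) and skin (-0.98 ± 0.18), and btr24 rose (4.1 ± 0.70, 3.90 ± 0.54 and 1.49 ± 0.37). BX537350.1 and BX572630.2 also rose, and si:dkey-281i8.1 and zgc:171500 fell. Brain and liver shared 18 calls (14 higher and 4 lower in both, 2.04 expected in the same direction), brain and skin 45 (19 higher, 21 lower, 5 opposite, 5.18 expected) and liver and skin 13 (8 higher, 4 lower, 1 opposite, 2.31 expected).

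Between controls of the 8-week and the 3-week sampling, all genes named here having been chosen after their values were seen, cry-dash (-1.08), ddb2 (-1.29) and xpc (-0.63) were lower in brain. The cell death gene bbc3 was higher in liver (4.72) and skin (1.27). Liver and skin shared 239 calls for this time difference, 94 higher and 140 lower in both and 5 opposite, where 26.1 were expected in the same direction. The contrast holds everything that differed between the samplings, and no explanation was tested.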
